A study of Mus musculus with 15 samples.

How the data were processed

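Cerebella of FVB mice of 3 genotypes were studied, 5 libraries each: wild type, ATXN1[82Q] and ATXN1[82Q]V591A;S602D, both transgenes under the Pcp2 promoter. Per the labels' protocols, libraries were made from 10 ng of total RNA with a kit that primes from the poly(A) tail and at random positions, with inserts of 400 bp, and sequenced on a HiSeq machine. Per the submitters' processing notes, the authors aligned reads with STAR 2.5.3a to mm10 and made the deposited gene counts with HTSeq, and DESeq2 is named among their tools. The deposited count values are whole numbers that were not normalised. The strand setting, the counting mode and the annotation release are not given in the sources used here, so genes that overlap on opposite strands may share or lose counts. Reads outside any gene were 16.8% to 18.2% of the reads, ambiguous reads 1.18% to 1.25% and multiply aligned reads 12.8% to 14.6%.

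Groups were taken from the genotype labels. Gene positions, biotypes, lengths and GC content came from GENCODE M21 (GRCm38), where 23376 of the 24421 symbols were found, a further 645 through a RefSeq synonym, and 400 were not found. No 2 libraries of a genotype were duplicates (chi-square per degree of freedom from 5.7 to 40.6 over 30 pairs). Replicate numbers did not pair the libraries: 4 of 15 same-number pairs correlated above 0.1 (median -0.109).

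Genes were tested with the edgeR 4.0.16 quasi-likelihood F-test in R 4.3.3, with all 15 libraries in one fit, a mean per genotype, TMM normalisation (factors 0.968 to 1.04) and filterByExpr with a minimum count of 10. Calls were made at a Benjamini-Hochberg adjusted p under 0.05 over 15843 genes in each of the 3 comparisons. The common biological coefficient of variation was 0.102. Log2 CPM used a prior count of 2, and CPM of single genes were TMM-scaled. Intervals and p-values cover the spread between libraries, and amplified reads without molecular identifiers are not independent molecules.

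Gene lists were tested with camera and fry from limma 3.58.1, with adjusted values over 25 lists and the 3 comparisons. camera compares a list with other genes, with a preset correlation of 0.01 or an estimated one. With the preset 42 of 75 tests passed and with an estimated correlation 15 did. These were the Purkinje cell and the metabotropic glutamate and calcium lists in all 3 comparisons, the microglial, channel, cholecystokinin and ataxia lists in both comparisons of ATXN1[82Q], and the glutamate list in ATXN1[82Q] against wild type. The fry test asks whether the genes of a list move one way on balance and does not compare the list with others. Means of each list per library were compared by 2-sided exact permutation tests, adjusted over the same 75, which were added after the data were examined. The lists were markers of Purkinje cells, granule cells, interneurons, Bergmann glia and astrocytes, oligodendrocytes, their precursors, microglia, endothelial and mural cells, choroid plexus and ependyma, and brainstem neurons, and genes of CIC targets, ATXN1 and its partners, metabotropic glutamate and calcium signalling, potassium and sodium channels, glutamate receptors and transporters, GABA and glycine transmission, cholecystokinin signalling, inherited ataxias, immediate early response, heat shock, unfolded protein response, cholesterol synthesis, nuclear-encoded respiratory chain, type I interferon response and sex linkage.

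Of 5 red blood cell genes 4 were removed by the count filter, and none of 9 mitochondrially encoded genes is in the count tables, so these lists were not tested. The groups, tests, gene lists, rule for named genes and most alternatives were chosen before the data were examined. Named genes were, per comparison, the 8 largest rises and 8 largest falls among called protein-coding genes with a mean log2 CPM of at least 2 and no overlap between genotypes, up to 4 called members of each list, and always Atxn1, Atxn1l, Cic, Pcp2, Calb1, Etv4, Etv5, Spry4 and Cck. Some genes that this rule takes are not reported here. Other genes in the text, such as Foxp2, Cckbr, Kcnn2, Grin2d, Elovl5, Glra1, Glra2, Spred3, Shc3, Bag3, Ttr and Xist, and comparisons of Itpr1 and Slc1a3 outside the rule, were chosen after their values were seen.

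The share of change kept was the ratio of mean log2 fold changes, oriented by the direction of choice, with a bootstrap of 2000 draws over genes. The pipeline was tested on simulated data with known changes: of genes changed 1.5-fold 75 of 100 were called, of those changed 2-fold 81 of 97, with 4 false calls of 160, and a share of 50% was estimated as 52.5%. Alternatives were DESeq2 1.42.0, RLE size factors, no count filter, only the genotypes compared in the fit, the replicate number as a block, each library left out in turn, and an estimated correlation in camera. Ttr as a covariate, libraries with Ttr under 100 CPM alone and Xist as a covariate were added after the data were examined. Figures and tables were drawn with Python 3.11.15.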

Results

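Transcript levels were measured by RNA sequencing of cerebellar tissue from FVB mice of 3 genotypes, with 5 libraries each. Spinocerebellar ataxia type 1 is caused by an expanded glutamine tract in ATXN1, a nuclear protein that binds the transcriptional repressor CIC. In the transgenic mice the human ATXN1 coding sequence is driven by the Pcp2 promoter, which is active in Purkinje cells, the output neurons of the cerebellar cortex. One transgene, ATXN1[82Q], carries 82 glutamines. The other, ATXN1[82Q]V591A;S602D, carries the same tract and a pair of amino acid substitutions, which are known to weaken binding to CIC. It is called the substituted transgene here. The counts on genes per library ran from 38067915 to 40640811 in wild type, from 36467948 to 42818401 in ATXN1[82Q] and from 38468429 to 41480492 with the substituted transgene, and 15843 of 24421 genes had enough counts to be tested. The labels speak of mice but do not say that each library came from a separate animal, so p-values measure the spread between these libraries.

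Some libraries carried transcripts of tissue that borders the cerebellum. Ttr, the main transcript of the choroid plexus, ranged from 4.16 CPM to 5041 CPM. It exceeded 1000 CPM in 2 wild-type, 3 ATXN1[82Q] and 3 substituted libraries and stayed under 100 CPM in the other 7. The X-inactivation transcript Xist exceeded 1000 CPM in 2 libraries of each genotype. Mouse Atxn1 (chromosome 13, 45549755 to 45965008, GRCm38, minus strand) stood at 70.1 ± 9.03 CPM in wild type, 76.8 ± 6.46 in ATXN1[82Q] and 83.9 ± 4.04 with the substituted transgene (SD, n = 5). None of its 3 comparisons passed (edgeR adjusted p = 0.193, 0.112 and 0.202 for ATXN1[82Q] against wild type, the substituted transgene against wild type, and one transgene against the other). Human transgene reads enter these counts only as far as they align to the mouse gene, so the level of either transgene was not measured. Differences between the transgenic groups in transgene level, or in other traits of the mice, therefore cannot be told apart from the substitutions.

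In ATXN1[82Q] cerebella, compared with wild type to ask what the expanded protein changes, transcripts typical of Purkinje cells were lower and those of microglia were higher. Of 24 fixed Purkinje cell markers, 23 fell, with a median log2 fold change of -0.995, and Foxp2 did not pass (log2 fold change 0.08, adjusted p = 0.463). All 17 fixed markers of microglia, the immune cells of the brain, rose, with a median of 0.901. Granule cell markers fell by less (13 of 17, median -0.197; adjusted p = 0.128 with an estimated correlation). The genes that fell furthest included Cck, a neuropeptide precursor that fell 5.21-fold, and the largest rises included the astrocyte filament gene Gfap (3.12-fold) and the complement gene C4b (3.17-fold).

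The Purkinje cell genes covered calcium buffering, G-protein signalling and glutamate response. Calb1 (chromosome 4, 15881264 to 15908064), the calcium buffer calbindin, went from 1050 ± 49.6 to 452 ± 40.2 CPM (SD, n = 5; log2 fold change -1.21, SE 0.0656, adjusted p = 1.36e-09). Rgs8 (chromosome 1, 153653025 to 153700323), a regulator of G-protein signalling, went from 1287 ± 93.4 to 272 ± 14.4 CPM (log2 fold change -2.24, SE 0.12, adjusted p = 1.36e-09), and Car8 (chromosome 4, 8143362 to 8239041), which binds the IP3 receptor, from 1298 ± 63.6 to 463 ± 44.7 CPM. Pcp2 (chromosome 8, 3623371 to 3625545) went from 106 ± 3 to 58.1 ± 4.65 CPM. Its exons overlap those of Pet100 over 51.5% of their length, and without strand these reads cannot be told apart, so its value is uncertain. The count was 23 lower both over all genes and adjusted over the list alone. The marker mean per library was -1.01 ± 0.0712 on the log2 scale against 0 ± 0.0624 in wild type (SD, n = 5). The 2-sided exact permutation p was 0.00794, the smallest 5 against 5 can give (adjusted p = 0.0198), and the list differed from other genes with an estimated correlation (limma camera, adjusted p = 0.00551).

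Genes of metabotropic glutamate and calcium signalling, a list that shares members with the Purkinje cell markers, fell as a block. All 22 fell, also when adjusted over the list alone (median -0.946; adjusted p = 0.00551 with an estimated correlation). Itpr1, the IP3 receptor that releases calcium from the endoplasmic reticulum, went from 3769 ± 372 to 1372 ± 123 CPM (SD, n = 5). Of 18 potassium and sodium channel genes, 13 fell and Kcnn2 rose, with the same counts adjusted over the list alone (adjusted p = 0.0192 with an estimated correlation); Kcnab1 fell 2.4-fold. Of 19 glutamate receptor and transporter genes, 15 fell and Grin2d rose (15 lower and 3 higher adjusted over the list alone; adjusted p = 0.0435 with an estimated correlation); Grik1 fell 2.13-fold. Of 27 inherited ataxia genes, 11 fell and Elovl5 rose, unchanged when adjusted over the list alone (adjusted p = 0.0226 with an estimated correlation). Some of those that fell, such as Itpr1, are also members of the calcium and Purkinje lists. In the GABA and glycine list of 14, 7 fell and 4 rose, among them Glra1 and Glra2 (8 and 4 adjusted over the list alone; adjusted p = 0.0818 with an estimated correlation). Libraries with Ttr under 100 CPM alone gave 6 lower and 0 higher by edgeR (8 and 2 at an unadjusted p under 0.05). The list mean was 0.0978 and 0.0645 above wild type in replicates 2 and 5 of ATXN1[82Q], where the mean of brainstem neuron markers was 1.82 and 2.82. In its other 3 libraries the list mean ran from -0.206 to -0.139 and the brainstem mean from 0.0408 to 0.259. The GABA-B receptor genes Gabbr1 and Gabbr2 fell 1.93-fold and 1.72-fold, and the granule cell receptor gene Gabra6 fell 1.41-fold. Cck (chromosome 9, 121489824 to 121495694) went from 27.4 ± 2.37 to 5.25 ± 0.735 CPM (adjusted p = 7.67e-09), while its receptor gene Cckbr did not pass (log2 fold change 0.42, adjusted p = 0.178); 1 of the 2 tested genes of that list fell, also adjusted over the list alone, with an adjusted p = 0.0455 with an estimated correlation.

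Markers of other cell types moved in both directions. Among markers of granule cells, the most numerous neurons of the cerebellum, Calb2 fell 1.46-fold and Cbln3 fell 1.37-fold in the tissue. Adjusted over the list alone 15 markers were lower, and the marker mean was -0.273 ± 0.0503 (SD, n = 5; exact permutation adjusted p = 0.0198; adjusted p = 0.128 with an estimated correlation). C1qa (chromosome 4, 136895917 to 136898803), a complement component made by microglia, went from 16.5 ± 1.18 to 37.9 ± 2.48 CPM, and Trem2, a microglial surface receptor, rose 2.56-fold. The microglial marker mean was 0.889 ± 0.0976 (SD, n = 5; exact permutation adjusted p = 0.0198; adjusted p = 0.00551 with an estimated correlation), with 17 higher also adjusted over the list alone. Of 17 markers of Bergmann glia and astrocytes, 8 rose and 4 fell (10 and 4 adjusted over the list alone; adjusted p = 0.0894 with an estimated correlation). Gfap (chromosome 11, 102887336 to 102900912) went from 136 ± 17.9 to 425 ± 36.1 CPM and the water channel gene Aqp4 rose 1.5-fold, while the glutamate transporter gene Slc1a3 and Hopx fell. Of 14 oligodendrocyte markers, 8 rose (12 adjusted over the list alone; adjusted p = 0.444 with an estimated correlation), such as Cldn11 at 1.32-fold. Their mean was highest in replicates 5 and 2 of ATXN1[82Q] (0.517 and 0.326), where the mean of brainstem neuron markers was also highest (2.82 and 1.82). In the other ATXN1[82Q] libraries it ran from 0.203 to 0.234, and in wild type from -0.344 to 0.192. Of 6 precursor markers, 3 rose (4 adjusted over the list alone; adjusted p = 0.276 with an estimated correlation), led by Gpr17 at 1.37-fold. Among interneuron markers 5 of 9 rose, the same count adjusted over the list alone (adjusted p = 0.276 with an estimated correlation), and among endothelial and mural markers 3 of 12 rose, Pdgfrb, Vtn and Kcnj8, also adjusted over the list alone (camera adjusted p = 0.0672). That list was called without the count filter (0.0455), without replicate 4 or 5 of ATXN1[82Q] (0.0394 and 0.0349), with Ttr as a covariate (0.0472) and with Ttr under 100 CPM only (0.0235), in a range of 0.0235 to 0.146 over the alternatives with the preset correlation. It was not called with an estimated correlation (camera adjusted p = 0.323). The call of Kcnj8 was lost without replicate 4 of ATXN1[82Q] (edgeR adjusted p = 0.0505) or replicate 4 of wild type (0.0552). Interferon response genes rose in 8 of 11 cases (9 adjusted over the list alone; adjusted p = 0.0517 with an estimated correlation), with Oasl2 at 1.92-fold and Ifitm3 at 1.61-fold. The exact permutation test of the list mean gave an adjusted p = 0.0198 for the astrocyte, oligodendrocyte, precursor, interneuron, endothelial and mural, and interferon lists (differences of 0.197, 0.297, 0.254, 0.185, 0.151 and 0.614). With Ttr under 100 CPM only, 8 granule cell markers were called lower (median -0.187) and 2 interneuron markers higher (median 0.13).

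Among 17 known CIC target genes, 6 fell and 1 rose (7 and 1 adjusted over the list alone). Those that fell included the ETS factor genes Etv1 and Etv4 and the phosphatase gene Dusp4, and the gene that rose was the cyclin Ccnd1 (1.39-fold). Etv4 (chromosome 11, 101769742 to 101785371) went from 17.7 ± 2.62 to 10.5 ± 0.889 CPM (SD, n = 5; log2 fold change -0.75, SE 0.0926, adjusted p = 1.03e-05). Etv5 and Spry4 did not pass (log2 fold change -0.32 and -0.41, adjusted p = 0.0784 and 0.17). The list was called lower by camera with the preset correlation (adjusted p = 0.0147) and by fry (adjusted p = 0.00363), which does not compare it with other genes. It was not called by camera with an estimated correlation (adjusted p = 0.276). The exact permutation test of its mean gave an adjusted p = 0.051 for a difference of -0.239. Cic itself did not pass (log2 fold change -0.08, adjusted p = 0.163), nor did its ATXN1-family partner Atxn1l (-0.13, adjusted p = 0.0614). Among 10 genes of ATXN1 and its partners 2 fell, Rora and Rbm17 (1 adjusted over the list alone; camera adjusted p = 0.289). The call of Rbm17 was lost when replicate 1, 4 or 5 of ATXN1[82Q] or replicate 1, 2, 3 or 4 of wild type was left out (edgeR adjusted p from 0.0571 to 0.104).

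Across all genes, edgeR called 4993 for ATXN1[82Q] against wild type, 2635 higher and 2358 lower. Of these, 946 were higher and 349 lower by over 1.5-fold, and 371 and 147 by over 2-fold. The median of the mean log2 CPM was -0.167 for the 371 and 3.28 for the 147, so the rises over 2-fold were mostly in genes of low level. In 3034 of all 15843 tested genes, called or not, the values of both genotypes did not overlap, where chance gives 0.794%. Libraries with Ttr under 100 CPM alone (2 or 3 per genotype) gave 3234 genes. Of the genes higher by over 2-fold, 240 were also called in those libraries, and of those lower by over 2-fold, 128.

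**Figure D1:**
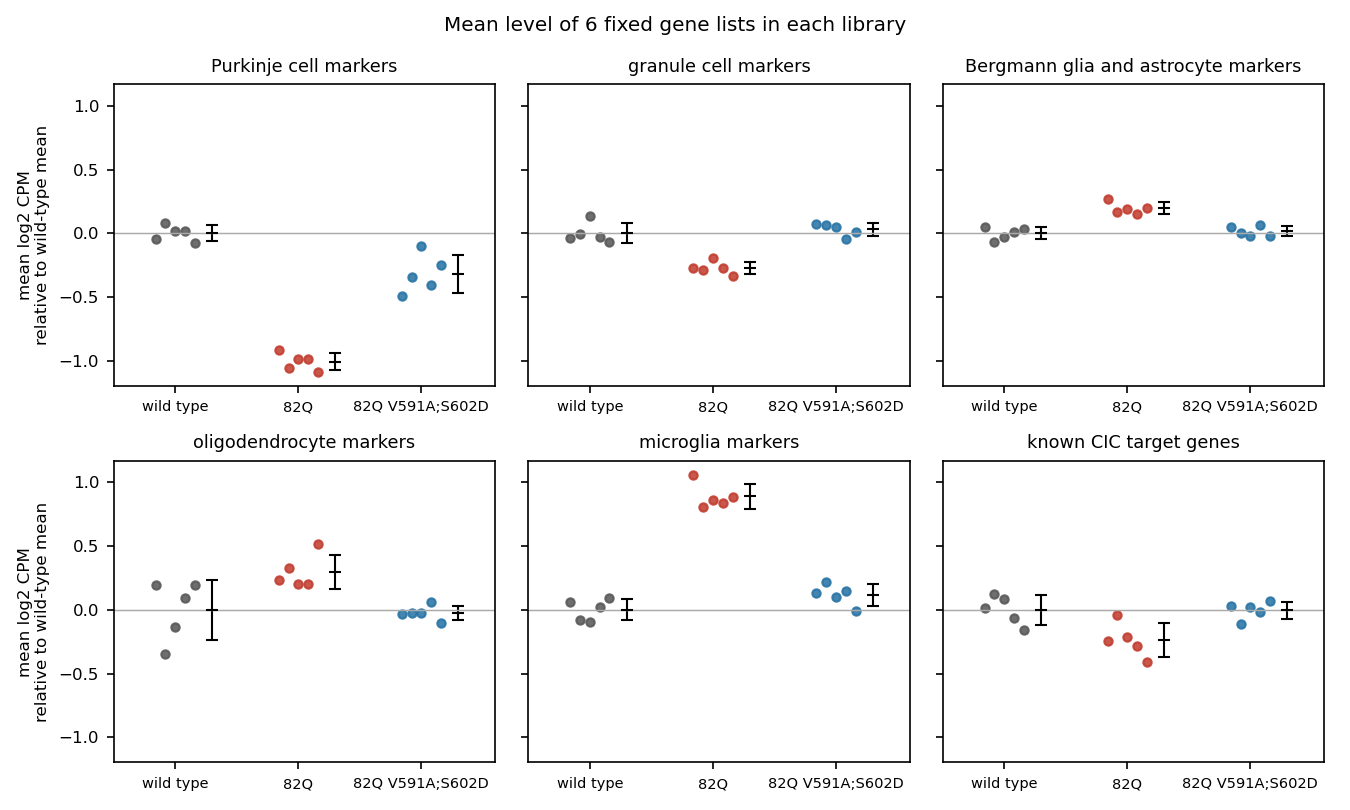
Mean log2 CPM of 6 fixed gene lists relative to the wild-type mean (vertical axis) in each of 15 libraries (points), with the mean and SD of 5 libraries per genotype (black bars). The Purkinje cell mean lies at -1.01 in ATXN1[82Q] and -0.319 with the substituted transgene, and the microglial mean at 0.889 and 0.116.

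With the substituted transgene, compared with wild type to ask what the expanded protein changes when its binding to CIC is weakened, Purkinje cell genes were lower, by less than in ATXN1[82Q], and few genes of other cell types passed. Of the 24 Purkinje cell markers, 14 fell and none rose (20 and 1 adjusted over the list alone), with a median log2 fold change of -0.341. Pcp4 went from 525 ± 18 to 371 ± 44.7 CPM and Calb1 from 1050 ± 49.6 to 795 ± 67.6 CPM (SD, n = 5). Pcp2 did not pass (103 ± 6.85 CPM, log2 fold change -0.04, adjusted p = 0.829), and neither did Itpr1 (-0.34, adjusted p = 0.0782) or Cck (-0.54, adjusted p = 0.083). Genes with the largest falls included Gchfr, which encodes a regulator of the tetrahydrobiopterin pathway (3.18-fold, from 11.8 ± 0.759 to 3.71 ± 1.8 CPM), and the growth factor gene Fgf7 (2.08-fold).

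The Purkinje cell list was called in every form of its test (exact permutation adjusted p = 0.0198 for a mean of -0.319 ± 0.151, SD, n = 5; adjusted p = 0.0192 with an estimated correlation). So was the metabotropic glutamate and calcium list, of which 10 of 22 fell (18 adjusted over the list alone; median -0.309; adjusted p = 0.0192 with an estimated correlation). Of the channel genes 4 of 18 fell (6 adjusted over the list alone; adjusted p = 0.0568 with an estimated correlation), among them Kcna6 and Kcng4, each 1.35-fold. Grik1 was the 1 of 19 glutamate genes that fell (1.49-fold; 3 adjusted over the list alone; adjusted p = 0.276 with an estimated correlation). The preset call of that list was lost without replicate 4 of the substituted transgene (camera adjusted p = 0.111). Of the GABA and glycine list Gabbr1 fell (4 lower and 1 higher adjusted over the list alone; camera adjusted p = 0.0672), with a median of -0.0353 and a mean of 0.00592 that differ in sign. The ataxia gene list was called lower with the preset correlation (camera adjusted p = 0.000234) and by fry (adjusted p = 0.0144). It was not called with an estimated correlation (camera adjusted p = 0.0894) or by the exact permutation test of its mean (adjusted p = 0.0784). Rora fell 1.17-fold among ATXN1 and its partners (1 lower and 2 higher adjusted over the list alone; camera adjusted p = 0.0926), a call lost without replicate 1, 2 or 4 of the substituted transgene or replicate 2 or 4 of wild type (edgeR adjusted p from 0.052 to 0.0682).

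The cell types other than Purkinje cells gave few calls. No microglial marker passed in edgeR; 6 of 17 were higher at an unadjusted p under 0.05, 1 was called by DESeq2 and 1 adjusted over the list alone. Their mean lay 0.116 ± 0.0841 above wild type (SD, n = 5; exact permutation adjusted p = 0.113), and the preset call (adjusted p = 0.000411) was lost (adjusted p = 0.276 with an estimated correlation). No granule cell marker passed in edgeR, in DESeq2 or adjusted over the list alone (2 higher and 1 lower at an unadjusted p under 0.05; mean 0.0315, exact permutation adjusted p = 0.585). Of the astrocyte list none passed in edgeR (2 higher and 1 lower at an unadjusted p under 0.05, 1 by DESeq2, 1 adjusted over the list alone; camera adjusted p = 0.422). Oligodendrocyte markers gave no edgeR or DESeq2 call and none at an unadjusted p under 0.05 (camera adjusted p = 0.529), and their precursors gave 1 at an unadjusted p under 0.05 and none in edgeR or DESeq2 (camera adjusted p = 0.813; median -0.00804 and mean 0.0268, which differ in sign). Prkcd fell among the interneuron markers (adjusted p = 0.0385; 1 adjusted over the list alone; camera adjusted p = 0.288). That call was lost when any of 8 single libraries was left out, all but wild-type replicates 3 and 4 (edgeR adjusted p from 0.0512 to 0.13).

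None of the 17 CIC target genes passed in edgeR with the substituted transgene. At an unadjusted p under 0.05, 3 were lower and 1 higher, DESeq2 called 1, and 1 fell and 1 rose adjusted over the list alone. The list's median was 0.0272 and its mean -0.00788, which differ in sign, and camera put the list lower (adjusted p = 0.891). Etv4 stood at 14.3 ± 1.34 CPM (SD, n = 5; log2 fold change -0.31, adjusted p = 0.126), Etv5 at 79.2 ± 4.03 (0.03, adjusted p = 0.957) and Spry4 at 14.4 ± 4.34 (-0.26, adjusted p = 0.686). Cic and Atxn1l did not pass (log2 fold change 0.04 and 0.03, adjusted p = 0.779 and 0.89).

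Genes that rose with the substituted transgene included Creb5, a transcription factor gene (1.73-fold), the adhesion protein gene Tenm2 (1.45-fold), and Bbc3, which promotes apoptosis (1.32-fold). In all, edgeR called 223 genes, 33 higher and 190 lower. The number higher was 15 to 17 without replicate 1, 2 or 4 of the substituted transgene or replicate 2 or 4 of wild type, and the number lower was 120 and 125 without replicates 2 and 4 of the substituted transgene in turn. By over 1.5-fold 9 were higher, or 3 without replicate 4 of the substituted transgene or replicate 3 of wild type and 5 without replicate 4 of wild type, and 24 were lower, or 14 and 61 without replicates 1 and 3 of the substituted transgene in turn. The values of both genotypes did not overlap in 500 of all 15843 tested genes, where chance gives 0.794%. Libraries with Ttr under 100 CPM alone gave 149, 11 higher and 138 lower, of which 6 and 44 by over 1.5-fold. DESeq2 called 429, 108 higher and 321 lower, and leaving out replicate 2 or 4 of the substituted transgene or replicate 2 of wild type gave 136, 142 and 143 by edgeR. In simulated data with 5 libraries per genotype, 44 of 100 genes changed 1.22-fold and 61 of 97 changed 1.41-fold were called, so changes of this size were often missed.

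**Figure D2:**
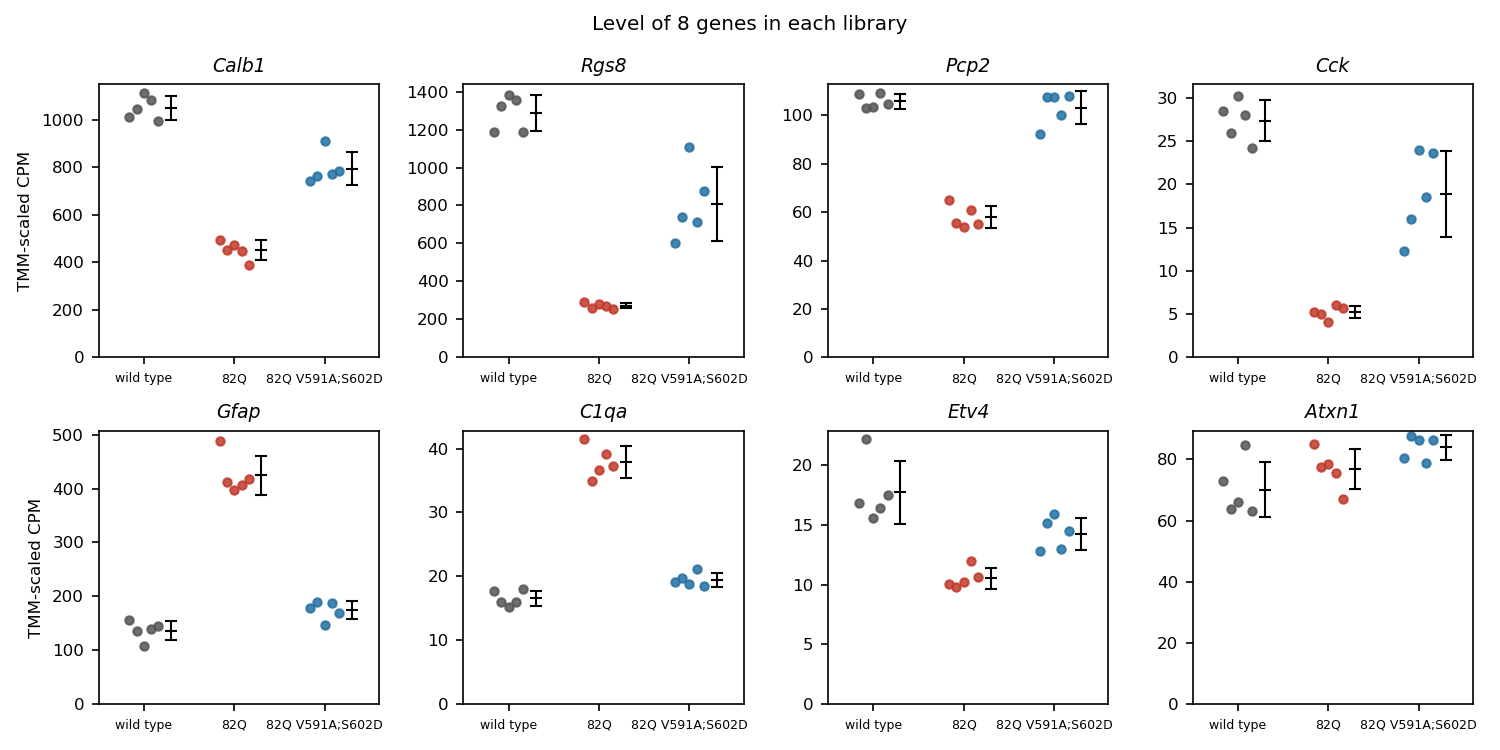
TMM-scaled CPM (vertical axis, from 0) of 8 genes in each of 15 libraries (points), with the mean and SD of 5 libraries per genotype (black bars). Calb1 falls from 1050 CPM in wild type to 795 with the substituted transgene and 452 in ATXN1[82Q], and C1qa stands at 16.5, 19.4 and 37.9 CPM.

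The transgenes were set directly against each other to ask how their effects differ. ATXN1[82Q] cerebella had lower levels of Purkinje and granule cell genes and higher levels of microglial genes than those with the substituted transgene. Of 24 Purkinje cell markers 23 were lower (also adjusted over the list alone; median -0.691; adjusted p = 0.0117 with an estimated correlation), with Rgs8 at 272 ± 14.4 against 808 ± 195 CPM and Car8 at 463 ± 44.7 against 939 ± 94.6 CPM (SD, n = 5). All 17 granule cell markers were lower, also adjusted over the list alone (median -0.275; adjusted p = 0.0517 with an estimated correlation; exact permutation adjusted p = 0.0198 for the mean). All 17 microglial markers were higher, also adjusted over the list alone (median 0.812; adjusted p = 0.00551 with an estimated correlation), with C1qa at 37.9 ± 2.48 against 19.4 ± 1.09 CPM. With Ttr under 100 CPM only, which leaves 2 libraries of each transgene, 19 Purkinje and 7 granule cell markers were lower (medians -0.565 and -0.254) and 15 microglial markers higher (median 0.91). Tnc, an extracellular matrix gene, was 3.94-fold lower, Cck 3.59-fold lower, and Gfap 2.44-fold higher.

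All 22 genes of metabotropic glutamate and calcium signalling were lower, also adjusted over the list alone (median -0.574; adjusted p = 0.0192 with an estimated correlation), with Itpr1 2.18-fold lower. Of the channel genes 11 were lower and 1 higher, the same adjusted over the list alone (adjusted p = 0.0435 with an estimated correlation). Of the glutamate genes 13 were lower and 1 higher (14 and 3 adjusted over the list alone; adjusted p = 0.0517 with an estimated correlation). For GABA and glycine genes the counts were 7 and 1 (7 and 2 adjusted over the list alone; adjusted p = 0.128 with an estimated correlation), and 4 and 0 by edgeR with Ttr under 100 CPM only (6 and 2 at an unadjusted p under 0.05). Ataxia genes gave 10 lower and 1 higher (11 and 1 adjusted over the list alone; adjusted p = 0.0435 with an estimated correlation). Cck was the 1 of 2 cholecystokinin genes that differed, also adjusted over the list alone (adjusted p = 0.0435 with an estimated correlation).

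Of the CIC target genes 6 were lower, Etv1, Etv4, Spred3, Dusp4, Dusp5 and Shc3 (7 lower and 1 higher adjusted over the list alone). Etv4 stood at 10.5 ± 0.889 against 14.3 ± 1.34 CPM (SD, n = 5; log2 fold change -0.44, SE 0.0929, adjusted p = 0.00232). The difference of the list means, ATXN1[82Q] minus the substituted transgene, was -0.236 (exact permutation adjusted p = 0.0373; adjusted p = 0.261 with an estimated correlation). Of ATXN1 and its partners 5 were lower, also adjusted over the list alone (2 with Ttr under 100 CPM only; adjusted p = 0.185 with an estimated correlation), among them Rora and Atxn1l (-0.16, adjusted p = 0.0303). The call of Atxn1l was lost without replicate 2, 3 or 4 of ATXN1[82Q] or replicate 1 or 3 of the substituted transgene (edgeR adjusted p from 0.0545 to 0.0804). Cic (chromosome 7, 25267704 to 25294159) was 1.09-fold lower (295 ± 17.6 against 322 ± 8.65 CPM, SD, n = 5; adjusted p = 0.0455). The call was lost when any of 7 libraries was left out, replicates 1, 3 and 5 of ATXN1[82Q] or 1, 2, 3 and 5 of the substituted transgene (edgeR adjusted p from 0.06 to 0.124).

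Astrocyte markers gave 8 higher and 4 lower, also adjusted over the list alone (adjusted p = 0.0818 with an estimated correlation), oligodendrocyte markers 11 of 14 higher (12 adjusted over the list alone; adjusted p = 0.305 with an estimated correlation) and their precursors 4 of 6 (5 adjusted over the list alone; adjusted p = 0.276 with an estimated correlation). Interneuron markers gave 5 of 9 higher, also adjusted over the list alone (adjusted p = 0.276 with an estimated correlation), endothelial and mural markers 3 of 12, likewise adjusted over the list alone (camera adjusted p = 0.123), and interferon response genes 4 of 11 (7 adjusted over the list alone; adjusted p = 0.0728 with an estimated correlation). The exact permutation adjusted p of the list mean was 0.0198 for the astrocyte, oligodendrocyte, interneuron and interferon lists (differences of 0.182, 0.323, 0.122 and 0.472), 0.0373 for precursors (0.222) and 0.0784 for endothelial and mural markers (0.111). With Ttr under 100 CPM only, 6 astrocyte markers were higher and 1 lower, and 2 oligodendrocyte, 1 precursor and 1 interneuron marker were higher (medians 0.292, 0.283 and 0.178, against 0.35, 0.256 and 0.157 in all libraries). Across all genes 4454 differed, 2134 higher and 2320 lower, of which 572 and 197 by over 1.5-fold. Values did not overlap in 2835 of all 15843 tested genes, where chance gives 0.794%. Between libraries with Ttr under 100 CPM alone 1512 differed, 608 higher and 904 lower.

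The genes changed by the substituted transgene were nearly all changed by ATXN1[82Q] as well. Of 223, 216 changed in the same direction in both (30 higher, 186 lower), none in opposite directions (edgeR; 58 at an unadjusted p under 0.05 in both, 2 by DESeq2), and 7 passed with the substituted transgene alone. These 7, named after their values were seen, were Ehd1, Igip, Irs2, Pde2a, Prkcd, Snhg14 and Zc3h4, and all 7 also differed between the transgenes. Leaving out replicate 2 or 4 of the substituted transgene or replicate 2 of wild type gave 133, 137 and 141 shared genes, and DESeq2 gave 372.

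Both comparisons use the same wild-type libraries, which by itself makes their fold changes alike to a degree. Independent lists of these sizes would share 5.49 higher and 28.3 lower genes, which does not allow for the shared libraries. Across genes, which are not independent replicates, the fold changes correlated at 0.63 (0.503 in 20 simulations of unchanged groups), with a covariance of 0.0499 (0.0137 simulated, a difference of 0.0362), and 63.4% had the same sign (66.7% simulated). Neither simulated group held a change, whereas 4993 genes were called for ATXN1[82Q]. The simulated correlation and same-sign percentage are therefore no measure of chance for these data, and no conclusion is drawn from them. With wild-type replicates 1 and 2 for ATXN1[82Q] and 3 to 5 for the substituted transgene, 3 genes passed for the latter, all 3 shared. The correlation was 0.427 and the covariance 0.0345. With these wild-type libraries exchanged, 1 passed, it was shared, and the values were 0.421 and 0.0401. These fits held fewer wild-type libraries, so their counts cannot be set against those of the full fit. Both covariances, from separate wild-type libraries, exceeded the 0.0137 simulated for shared ones. Across genes as a set this argues against shared wild-type libraries as the only source of the likeness. A part from bordering tissue was not tested.

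**Figure D3:**
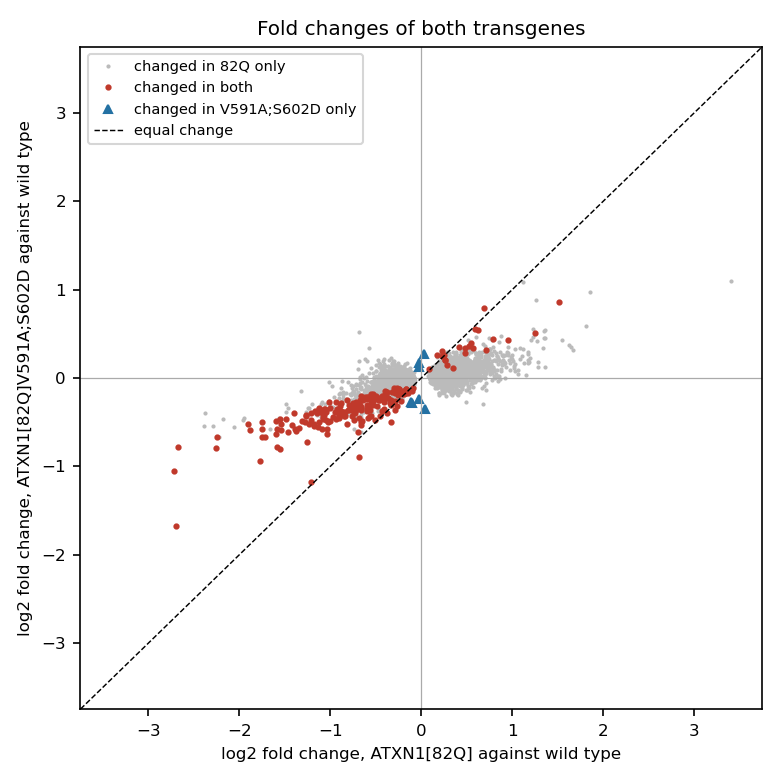
Log2 fold change against wild type for ATXN1[82Q] (horizontal axis) and ATXN1[82Q]V591A;S602D (vertical axis) of the 3988 genes changed by either that have a mean log2 CPM of at least 2, of 5000 changed in all. Genes changed by both (red) lie mostly between the horizontal axis and the dashed line of equal change.

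The share of the ATXN1[82Q] change kept with the substituted transgene was estimated on other libraries than those used to choose the genes. Over 1187 genes chosen on replicates 1 and 2 of wild type and ATXN1[82Q], replicates 3 to 5 of the substituted transgene showed 26.9% of the ATXN1[82Q] change (95% bootstrap interval over genes 25.4 to 28.5). The share was 27.9% for genes chosen as higher and 26.2% for those chosen as lower. Single libraries spread far more than that interval, at 16.2%, 43.4% and 21.6% (mean 27.1%, SD 14.4, n = 3), against -12.8%, -0.525% and 13.3% in wild type. Ttr in replicates 3 to 5 was 2208, 3555 and 35.2 CPM with the substituted transgene and 8.03, 3349 and 5041 CPM in ATXN1[82Q]. In wild type it was 43.9, 4.16 and 3771 CPM, so bordering tissue was uneven between the genotypes. The share was not estimated with a Ttr setting, so the part of bordering tissue in it was not tested. Choosing on replicates 3 to 5 and estimating on 1 and 2 gave 20.2% over 2707 genes. The share is an average over the chosen genes and does not hold for each cell type. Over all 5 libraries, the Purkinje cell marker mean was -1.01 in ATXN1[82Q] and -0.319 with the substituted transgene. The same means were 0.889 and 0.116 for microglia, -0.273 and 0.0315 for granule cells, and 0.297 and -0.0257 for oligodendrocytes.

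Some genes were changed by both transgenes without a detected difference between them. Of 54 such genes, 17 higher and 37 lower, examples chosen after their values were seen were Mdfi (log2 fold change -1.21 in ATXN1[82Q] and -1.17 with the substituted transgene; 95% interval of the difference -0.40 to 0.31), Cpeb1, an RNA-binding regulator of translation (-0.51 and -0.48; -0.17 to 0.11), and Tenm2 (0.63 and 0.54; -0.09 to 0.27). The intervals leave room for differences of these sizes, so equal change was not shown.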

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

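The tests of Ttr, of unequal marker change, of microglia against oligodendrocytes, of sex and of a wrong label were chosen only after the results were seen, and the first forms of some were replaced; the tests of GC content and length and of other splits were planned. A value was listed when the gap between one library and the nearest of its genotype exceeded 0.71 of the range of 5 libraries. This held for 31 of 480 groups (6.46%), where chance gives about 5%, so single values carry little weight.

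With the substituted transgene, replicate 3 had the highest Calb1 (912 CPM, others 741 to 785), Kcnab1 (155 CPM, others 122 to 130) and Ppp1r17 (287 CPM, others 231 to 247), all nearer to wild type. Replicate 5 had the highest Hspa8 (1670 CPM, others 1430 to 1500), Hsph1 (221 CPM, others 159 to 172), Herpud1 (101 CPM, others 88.9 to 90.1) and mean of heat shock genes (0.434, others 0.114 to 0.172, log2 CPM relative to wild type). Replicate 1 had the highest Cbln3 (1710 CPM) and Nxph1 (15.8 CPM), replicate 2 the highest C1qb (14.7 CPM) and Cspg4 (7.61 CPM), and replicate 4 the highest Slc6a2 (0.829 CPM) and mean of cholesterol synthesis genes (0.0145).

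In ATXN1[82Q], replicate 1 had the highest Gfap (488 CPM, the others at most 418), Gpr17 (39.1 CPM), Lyz2 (28.4 CPM) and Trabd2b (7.7 CPM) and the lowest mean of respiratory chain genes (-0.101). Replicate 3 had the highest Ndufa9 (115 CPM). Replicate 5 had the highest Slc6a2, the noradrenaline transporter (6.86 CPM, others 0.0266 to 1.35), Egr1 (39.3 CPM), Olig1 (76.7 CPM), Col5a1 (11.1 CPM) and mean of cholesterol synthesis genes (0.11). In wild type, C4b was lowest in replicate 3 (8.07 CPM), Calb2 and the endothelial and mural mean in replicate 4 (308 CPM and -0.0645), and Etv5 in replicate 5 (54.4 CPM). Foxj1 was highest in replicate 5 (14.4 CPM), Gchfr in replicate 1 (13.1 CPM) and Trabd2b in replicate 2 (42.9 CPM).

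Purkinje cell markers were lower in ATXN1[82Q], with a median of -0.995. With Ttr as a covariate the median was -0.979, and after removal of the trend on GC content and length it was -1.06, which argues against bordering tissue and against that trend as the whole cause. Of 24 markers 15 lay over 3 standard errors from the median, which argues against an equal loss of all Purkinje cell RNA. A genotype effect on transcription in Purkinje cells may account for the pattern. Partial loss or shrinkage of Purkinje cells beside it stays open, since cells were not counted and some markers are made by other cells too.

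Microglial markers were higher in ATXN1[82Q], with a median of 0.901. With Ttr under 100 CPM alone the median was 1.05, which argues against bordering tissue. The microglial mean rose beyond the oligodendrocyte mean by 0.592, with no overlap between libraries (lowest 0.371 in ATXN1[82Q], highest 0.266 in wild type), which argues against a lower Purkinje cell share that raises all other cell types alike. More microglia, or more of these transcripts per cell, may follow from the genotype, and these data do not separate them.

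The Purkinje cell marker mean spread with the substituted transgene (SD 0.151, against 0.0624 in wild type). On this mean replicate 3 lay nearest wild type, at -0.102 against -0.492 to -0.246 in the other 4 and -0.0735 in the lowest wild-type library. On genes changed by both transgenes replicate 3 lay at 36.4% of the mean of the other 4. The genes were called in both transgene comparisons without it and without 1 wild-type library at a time (229 to 274 genes), and the wild-type libraries held out in this way lay at -10.6% to 15.7% (SD 10.7, n = 5), which argues against a wild-type library under a wrong label. On genes chosen in ATXN1[82Q] alone the gap was small, at 16.2% of the ATXN1[82Q] change against at most 13.3% in 3 wild-type libraries. The 2 libraries with high Xist had a mean of -0.45 and the other 3 one of -0.231, a difference of -0.219 (2-sided exact permutation p = 0.2, smallest possible 0.1). Sex cannot be told apart from other differences between animals with so few libraries. Transgene level, which was not measured, stays open for this spread and for the smaller change with the substituted transgene.

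Of the 126 splits of each 10 libraries, 100 were drawn. For changed genes 1 split, the real one, gave as many in ATXN1[82Q] against wild type (4993, highest other 872), 1 in the substituted transgene against wild type (223, highest other 124) and 1 between the transgenes (4454, highest other 1). The smallest share that 100 draws can give is 1 of 100, so chance is unlikely for these counts but is not excluded. For the number of lists called with the preset correlation, 10 splits gave as many in ATXN1[82Q] against wild type (15, highest other 17) and 21 in the substituted transgene against wild type (10, highest other 15), so chance cannot be excluded for these. Between the transgenes 2 did (17, highest other 17), a share under 0.05, although another split gave as many lists.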

How the results depend on the processing

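Models with Ttr or Xist as a covariate, and libraries with Ttr under 100 CPM alone, were chosen only after the data had been seen. No called list or named gene reversed its direction under any setting tried. Nor did the share of change kept, which was not estimated under the Ttr or Xist settings. Other called genes were not checked for reversal. The counts of changed genes in ATXN1[82Q] against wild type stayed within 1.5 times of 4993 with RLE size factors, without the count filter, with only the compared genotypes in the fit, with the replicate block and with each library left out (3909 to 5377), and those between the transgenes within 1.5 times of 4454 (3502 to 4648). Libraries with Ttr under 100 CPM alone gave 3234 and 1512 genes, with 2 or 3 libraries per genotype in place of 5. For the substituted transgene against wild type DESeq2 called 429 genes, of which 220 were among the 223 of edgeR, with 25.2% higher against 14.8%, and the cause was not tested. Leaving out 1 library gave 136 to 307 genes, the lowest without replicate 2 and the highest without replicate 3 of the substituted transgene. The genes shared by both transgenes numbered 372 with DESeq2 and 133 to 297 with 1 library left out. With an estimated correlation 15 list tests passed in place of 42, and 40 to 45 passed with the preset and 1 library left out. The share of change kept ran from 18.5% without replicate 4 of the substituted transgene to 32.7% without replicate 3. Over all single libraries left out, calls of named genes were kept in 1847 cases and lost in 173, and 9 were gained. Calls of lists were kept in 407 cases, lost in 13 and gained in 21. Small changes were often missed in simulated data with 5 libraries per genotype, where 44 of 100 genes changed 1.22-fold were called. Depth was not varied there, so its part in this was not tested.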

Other observations

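The look at single libraries for genes of cilia and the brainstem was chosen only after the results were seen. In ATXN1[82Q] against wild type, 4 of 18 cholesterol synthesis genes fell, with Idi1 1.32-fold and Cyp51 1.17-fold lower (4 adjusted over the list alone; camera adjusted p = 0.0962), and 4 of 22 respiratory chain genes fell, with Ndufa4 1.11-fold and Ndufa9 1.1-fold lower (4 adjusted over the list alone; camera adjusted p = 0.0959; exact permutation adjusted p = 0.0198 for a difference of -0.0525). With Ttr under 100 CPM only, none of the respiratory chain genes passed in edgeR (4 lower at an unadjusted p under 0.05), and with Ttr as a covariate the list was called (camera adjusted p = 0.0479, from 0.0479 to 0.194 over the alternatives with the preset correlation). The respiratory chain list was not called with an estimated correlation (camera adjusted p = 0.628). Of 15 heat shock genes Bag3 rose and Hspa4l fell (camera adjusted p = 0.941), of 15 unfolded protein response genes Atf3 rose and Atf4 fell (0.696), and of 11 immediate early genes Btg2 rose and Egr1 and Egr4 fell (1), with the same counts adjusted over each list alone. The calls of Hspa4l (replicate 4 of ATXN1[82Q], replicates 3 and 4 of wild type; edgeR adjusted p from 0.0558 to 0.0584) and Atf3 (replicates 3 and 4 of wild type; 0.0538 and 0.0547) were lost without any of the libraries named. Those of Egr1 (replicates 1 to 4 of ATXN1[82Q], 3 to 5 of wild type; 0.0549 to 0.102) and Btg2 (replicates 2, 4 and 5 of ATXN1[82Q], 1 to 4 of wild type; 0.0522 to 0.0993) were too. The medians and means of these 3 lists differ in sign (-0.0128 and 0.0182, -0.0857 and 0.0138, 0.0467 and -0.0335).

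With the substituted transgene, heat shock genes were higher as a list by the preset correlation (adjusted p = 2.13e-05; adjusted p = 0.276 with an estimated correlation), while no member passed in edgeR (6 higher at an unadjusted p under 0.05, 1 by DESeq2, 3 adjusted over the list alone). Unfolded protein response genes were also higher as a list (adjusted p = 0.0332; adjusted p = 0.356 with an estimated correlation), while its 1 called member, Atf4, fell and was lost without any 1 of the 10 libraries (edgeR adjusted p from 0.0539 to 0.13; 1 adjusted over the list alone). That list call was lost without replicate 3 or 5 of the substituted transgene or replicate 2 or 5 of wild type (camera adjusted p from 0.0537 to 0.179). Cholesterol synthesis genes (adjusted p = 0.00095; adjusted p = 0.39 with an estimated correlation) and respiratory chain genes (adjusted p = 0.000289; adjusted p = 0.276 with an estimated correlation) were lower as lists, and none passed in edgeR (3 and 5 at an unadjusted p under 0.05, 0 and 1 by DESeq2, 0 and 2 adjusted over the list alone). Between the transgenes, 5 heat shock genes and 6 unfolded protein response genes were lower in ATXN1[82Q] and 1 of the latter higher (adjusted p = 0.0247 and 0.0962 by camera; adjusted p = 0.549 and 0.491 with an estimated correlation), with 5, 7 and 1 adjusted over each list alone, and 3, 2 and 0 by edgeR with Ttr under 100 CPM only (7, 6 and 0 at an unadjusted p under 0.05). The heat shock list was lost without replicate 5 of either transgene (camera adjusted p = 0.0595 and 0.0909). Immediate early, cholesterol and respiratory genes gave no edgeR call between the transgenes (2, 2 and 2 at an unadjusted p under 0.05, 0, 0 and 1 by DESeq2; camera adjusted p = 0.697, 0.835 and 0.917).

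The substituted transgene gave no edgeR call among immediate early (1 by DESeq2 and 1 at an unadjusted p under 0.05; camera adjusted p = 0.411), interferon (0 and 0; 0.0579), endothelial and mural (0 and 1; 0.259), choroid plexus (0 and 0; 0.0614), brainstem (0 and 0; 0.529) and cholecystokinin genes (1 and 1; 0.277). In fits without a covariate, sex-linked genes gave no call in any comparison by edgeR or DESeq2 and none at an unadjusted p under 0.05 (camera adjusted p = 0.968, 0.917 and 0.917).

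Transcripts of ciliated and brainstem cells differed between libraries. Foxj1, a regulator of motile cilia, was the 1 choroid plexus and ependymal marker of 9 that rose in ATXN1[82Q] (16.5 ± 5.8 against 6.4 ± 4.64 CPM, SD, n = 5; edgeR adjusted p = 0.0114, from 0.000299 to 0.0331 under the alternatives; list camera adjusted p = 0.215). It was also called in libraries with Ttr under 100 CPM alone (log2 fold change 1.42, adjusted p = 0.00143), at 10.6 and 9.87 CPM in replicates 1 and 3 of ATXN1[82Q] against 2.95 to 5.04 CPM in replicates 2 to 4 of wild type. In the same libraries the cilia gene Rsph1 stood at 3.88 and 2.99 CPM against 1.02 to 1.59 CPM, Dnah9 at 2.84 and 2.53 against 0.677 to 1.08, and Cfap43 at 3.96 and 3.13 against 1.22 to 1.61. Between the transgenes that list gave no call by edgeR or DESeq2 (1 at an unadjusted p under 0.05; camera adjusted p = 0.606). Of 5 tested brainstem markers Slc6a2, Dbh and Slc5a7 rose in ATXN1[82Q] against wild type (4 adjusted over the list alone; camera adjusted p = 0.264) and Slc5a7 against the substituted transgene (4 adjusted over the list alone; camera adjusted p = 0.289). Slc6a2 stood at 6.86 CPM and Dbh at 6.23 CPM in replicate 5 of ATXN1[82Q], and at 1.35 and 2.28 CPM in replicate 2. All 3 calls against wild type were lost without replicate 5 of ATXN1[82Q] (Slc5a7 adjusted p = 0.0518 by edgeR), and those of Slc6a2 and Dbh also without replicate 2, 3 or 4 of wild type (0.0541 to 0.213 and 0.0503 to 0.162). The call of Slc5a7 between the transgenes was lost without replicate 5 of ATXN1[82Q] or replicate 3 of the substituted transgene (0.0523 to 0.081). The glycine receptor gene Glra1 was high in the same libraries (7.44 and 6.04 CPM, at most 0.717 CPM in the other 3 of ATXN1[82Q]).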
